A study of Homo sapiens with 6 samples.

How the data were processed

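RNA was sequenced from PC3 and LNCaP prostate cancer cells, each with a control shRNA or with 1 of 2 hairpins against PRMT5, in 6 libraries. The submitters' processing notes name CASAVA 1.8.2, STAR 2.5.2, DESeq2 1.18.1 and genome build GRCh38.p7. The read counter, strand setting and annotation release were not given in the sources used here. The deposited values are a signal per gene made by the authors, gene counts divided by 1 DESeq2 size factor per library. The values of each library were whole multiples of 1 step within a tolerance of 0.001 for 100% of genes, so whole reads were recovered, and the recovered factors matched median-of-ratios factors computed over these 6 libraries. All 6 columns belonged to a library, and 0 columns were left unassigned.

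The table held 58037 genes, 19240 of them at 0 in all libraries, and 57433 gene IDs (99.0%) matched GENCODE 29, which gave coordinates and gene types. The recovered reads per library numbered 18598512, 21388564 and 17216231 in PC3 and 15649593, 17283045 and 15367144 in LNCaP, each in the order shNC, shPRMT5-1, shPRMT5-3. Genes with a mean of at least 10 normalized counts were tested, 17509 in all, of which 13789 were protein coding. Intervals and floors cover counting error only, since reads carried no molecular identifiers.

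log2 of the deposited value + 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparison over both lines used cell line and knockdown as terms, with 3 residual degrees of freedom. The comparisons within PC3, within LNCaP and between them used a model of 4 group means with 2 residual degrees of freedom, and the comparison of the hairpins used line and construct as terms. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. With an estimated correlation camera has only the 2 or 3 residual degrees of freedom, so a call lost there decides little. Of 39 lists 38 had at least 3 tested members. Genes changed at least 1.5-fold the same way by both hairpins were counted beside simulated unchanged libraries that share a control. These were drawn with the spread between the 2 hairpin libraries of each line. No comparison had 3 libraries in each arm, so other splits of the samples were not counted, and no group had 4 libraries, so none was tested for outliers.

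Named genes were chosen by a rule written before the data were examined. It took PRMT5, then up to 10 genes per direction with the largest change among protein-coding genes that passed the threshold with a mean of at least 50 and the same direction in every hairpin library. Where fewer than 5 passed, the rule filled to 5 by the larger value of the smaller change over the hairpin libraries, and such genes are said not to have passed. From each list it took up to 4 members, called ones first and then the most abundant. Genes named outside the rule were chosen after their values were seen and are ARRDC4, CNTN1, KLK3, FKBP5, SLC38A2, UGT2B17, SYT4, ABCA12, RNA5-8S5, COLCA1 and NFASC.

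Alternatives were a pseudocount of 0.5 or 10, no filter, a mean of at least 50, TMM factors on top, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, the hairpin number as a replicate block, the mean of the effects in the lines, a 2-fold rule, and leaving out each library in turn. For the gene lists, TMM, the pseudocount, the filter and leaving out libraries were chosen after seeing the data. The tests were tested on simulated data with planted changes in 5 simulations: limma recovered 18.0, 64.5 and 83.4% of genes changed 2-, 4- and 8-fold over both lines, 0, 12.7 and 38.0% within PC3, 0, 14.9 and 37.3% within LNCaP, and 0% at each size for the difference between the lines. False limma calls numbered 2 over both lines, 0 within PC3, 20 within LNCaP and 0 for the difference. Over both lines the same change was planted in each line. The effects in the data were nearly unrelated between the lines, so that recovery need not carry over. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

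Shifts along chromosomes were examined after seeing the data, on 11816 protein-coding genes with a mean of at least 50, in windows of about 20 neighbouring genes and with 10000 permutations of gene positions per chromosome and library, 92 tests in all.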

Results

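Gene expression was measured by RNA sequencing in 2 human prostate cancer cell lines after knockdown of PRMT5, the arginine methyltransferase that places symmetric dimethylation on histones, Sm proteins and other substrates. PC3 is labelled androgen receptor negative and LNCaP androgen receptor positive. In each line 1 library came from cells infected with a control lentiviral shRNA (shNC), 1 from cells with hairpin shPRMT5-1 and 1 from cells with hairpin shPRMT5-3, for 6 libraries in all. The cells were infected for 48 hours and selected in puromycin at 1 ug per ml for 7 days. The libraries held 15367144 to 21388564 reads in genes. A floor of 3 reads, the number that a count of 0 allows, was worth 2.51 to 3.27 normalized counts. Expression values are the deposited DESeq2-normalized counts, and they carry the authors' scaling. Changes are log2 fold changes of normalized count + 1 ± standard error from limma. They understate the change of low genes. The 2 hairpins served as the replicates of knockdown and each single control was assumed to vary like the hairpin libraries. The p-values of single genes therefore measure only the spread between these libraries. Those of gene lists with a preset correlation, of Fisher's exact test and of permutations set genes against other genes, which are not replicates. Every printed adjusted p is from limma with Benjamini-Hochberg adjustment unless another tool is named, and intervals that rest on reads cover counting error only.

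PRMT5 itself (ENSG00000100462, GRCh38 chromosome 14, 22920511 to 22929585) was lower in every hairpin library than in the control of its line. In PC3 its normalized count was 744 with shNC, 212 with shPRMT5-1 and 474 with shPRMT5-3. In LNCaP it was 836 with shNC, 236 with shPRMT5-1 and 435 with shPRMT5-3. The log2 change over both lines was -1.30 ± 0.37 with an adjusted p of 0.412, so the target did not pass the threshold. The hairpin 1 libraries held less PRMT5 mRNA than the hairpin 3 libraries in both lines.

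**Figure D1:**
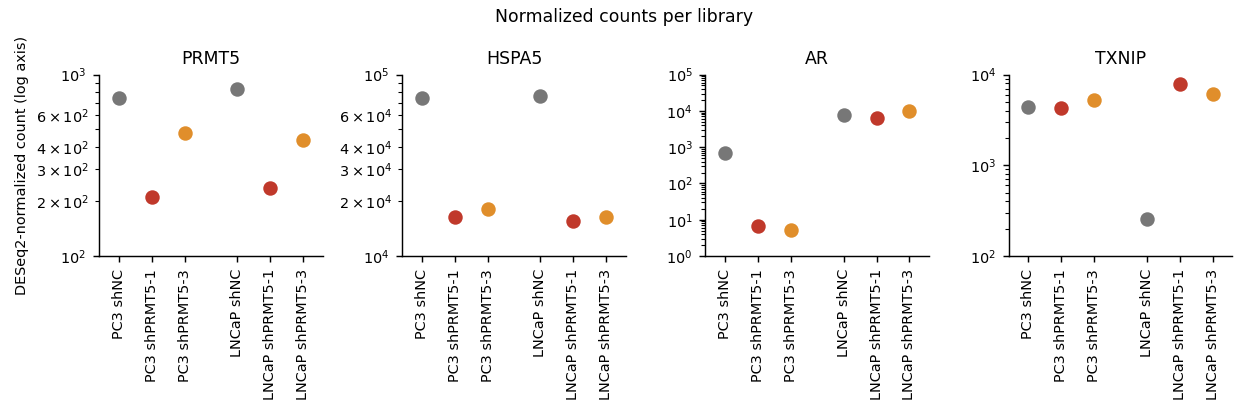
Normalized counts of PRMT5, HSPA5, AR and TXNIP in each of the 6 libraries, on a log axis; each point is 1 library. PRMT5 and HSPA5 sit below the control in all 4 hairpin libraries, AR stands at 708 in the PC3 control against 6.70 and 5.24, and TXNIP stands at 253 in the LNCaP control against 7878 and 6142 with the hairpins.

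The comparison over both lines asked which genes the knockdown changed in common. HSPA5, which encodes the endoplasmic reticulum chaperone BiP (ENSG00000044574.7, chromosome 9, 125234853 to 125241330), fell 4.51-fold (log2 change -2.17 ± 0.13, adjusted p 0.0189). Its normalized count was 74357 in the PC3 control against 16337 and 18103 with the hairpins, and 75737 in the LNCaP control against 15668 and 16500. It was the only gene that limma called among 17509 tested. The other genes that the naming rule took for a large change in the 4 hairpin libraries did not pass. Among these, HERPUD1, a component of the machinery that degrades endoplasmic reticulum proteins, stood at 3475 in the PC3 control and 15450 in the LNCaP control, against 1197 to 1520 in the 4 hairpin libraries (log2 change -2.49 ± 0.42, adjusted p 0.297, -1.47 without the LNCaP control). MANF, a secreted endoplasmic reticulum stress protein, had a log2 change of -1.52 ± 0.14 (adjusted p 0.0807). The insulin-like growth factor binding protein gene IGFBP4 (-1.65 ± 0.21, adjusted p 0.146) had 2.08 normalized counts in the LNCaP control and 0 with the hairpins. The potassium channel gene KCNN2 (-1.78 ± 0.33, adjusted p 0.329) was expressed mainly in LNCaP. The genes that the rule took in the other direction were EDN1, which encodes endothelin 1 (2.07 ± 0.36), SAMD9 (1.34 ± 0.15), CARD6 (1.27 ± 0.24), MALL (1.43 ± 0.37) and ZSWIM5 (2.25 ± 0.46), with adjusted p of 0.146 to 0.378. ZSWIM5 had 7.64 normalized counts in the PC3 control against 80.4 and 69.2, and 31.1 in the LNCaP control against 63.8 and 106, and stood at 1.37 without the PC3 control.

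Gene lists had been fixed before the data were examined, and 38 had at least 3 tested members. Over both lines 10 lists were called with a preset correlation between genes, 4 higher and 6 lower. The ATF4 and unfolded protein response genes fell together, with 33 of 33 tested members below 0. Of these 28 passed when adjusted over the list alone, 1 passed over all genes tested, and 18 were at least 1.5-fold lower in all 4 hairpin libraries (mean log2 change -1.25, adjusted p 7.47e-33, adjusted p = 0.989 with an estimated correlation). Among its abundant members, HSP90B1, the chaperone GRP94, had a log2 change of -1.40 ± 0.16, and the lectin chaperones CALR and CANX had -0.75 ± 0.18 and -0.44 ± 0.15. Cytosolic ribosomal protein genes fell slightly, 72 of 78 members being below 0 and 0 passing over the list alone (mean -0.20, adjusted p 3.32e-09, adjusted p = 0.989 with an estimated correlation). RPL4 stood at -0.36 ± 0.14 and RPLP0 at -0.30 ± 0.16. Replication-dependent histone genes rose (33 of 35 above 0, 0 over the list alone, mean 0.33, adjusted p 1.02e-07, adjusted p = 0.989 with an estimated correlation). The histone means with the hairpins were 0.60 and 0.72 in PC3, where nuclear ribosomal RNA also took a larger share of reads than in the control, and 0.14 and -0.14 in LNCaP. G1/S and DNA replication genes rose too (36 of 46 above 0, 0 over the list alone, mean 0.19, adjusted p 0.000487, adjusted p = 0.989 with an estimated correlation). Among them the helicase subunit gene MCM4 had 0.43 ± 0.23. The p53 targets fell (21 of 25 below 0, 5 over the list alone, mean -0.26, adjusted p 0.01, adjusted p = 0.989 with an estimated correlation). TNFRSF10B, a death receptor gene, stood at -0.63 ± 0.16 and CCNG1 at -0.67 ± 0.17. Without the PC3 control CCNG1 stood at -0.34, CANX at -0.27 and MCM4 at 0.66. MCM4 stood at 0.20 without the LNCaP control and at 0.23 without LNCaP shPRMT5-1. The remaining 5 lists were cholesterol synthesis (mean -0.48), nuclear-encoded oxidative phosphorylation (-0.10) and nuclear-retained RNAs (-0.26, 3 over the list alone), which fell, and 2 that rose. Those were epithelial junction and keratin genes (0.27) and interferon-stimulated genes (0.25, 1 over the list alone), the 5 lists having adjusted p of 0.000851 to 0.0387. These 5 calls were lost as well (adjusted p = 0.989 with an estimated correlation, for each). With a preset correlation, only the unfolded protein response and ribosomal protein calls held without each of the 6 libraries in turn. Without the PC3 control, cholesterol synthesis and oxidative phosphorylation turned to means of 0.22 and 0.15. The histone (-0.0020), epithelial (0.029) and interferon-stimulated lists (0.10) were then no longer called. Without the LNCaP control the calls of p53 targets (-0.05), G1/S genes (0.061) and nuclear-retained RNAs (-0.18) ended. G1/S genes were not called without LNCaP shPRMT5-1 either (0.046), nor were nuclear-retained RNAs (-0.21). Without LNCaP shPRMT5-3 the p53 (-0.18), epithelial (0.18), interferon-stimulated (0.089) and nuclear-retained calls (-0.29) ended. Without PC3 shPRMT5-3 the epithelial (0.17), interferon-stimulated (0.19) and oxidative phosphorylation calls (-0.068) ended, the last also without PC3 shPRMT5-1 (-0.059). Without the control of a line these values equal those of the other line, as for the unfolded protein response (-0.72 without the LNCaP control) and ribosomal proteins (-0.11 without the PC3 control). Without LNCaP shPRMT5-1 the interferon-stimulated and epithelial means were 0.45 and 0.42, and without LNCaP shPRMT5-3 the G1/S mean was 0.29.

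limma called 0 genes higher and 1 lower over both lines, with 1682 genes at an unadjusted p under 0.05 where chance gives 875, and edgeR called the same 0 and 1 on recovered reads. The excess over chance ended when PC3 shPRMT5-1 or PC3 shPRMT5-3 was left out. DESeq2 called 295 genes, 84 higher and 211 lower, HSPA5 among them. The HSPA5 call ended without any of the 6 libraries in turn (log2 change -2.24 to -2.11, adjusted p 0.104 to 0.507) and when the effects of the lines were averaged from a 4-group model (adjusted p 0.0995).

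**Figure D2:**
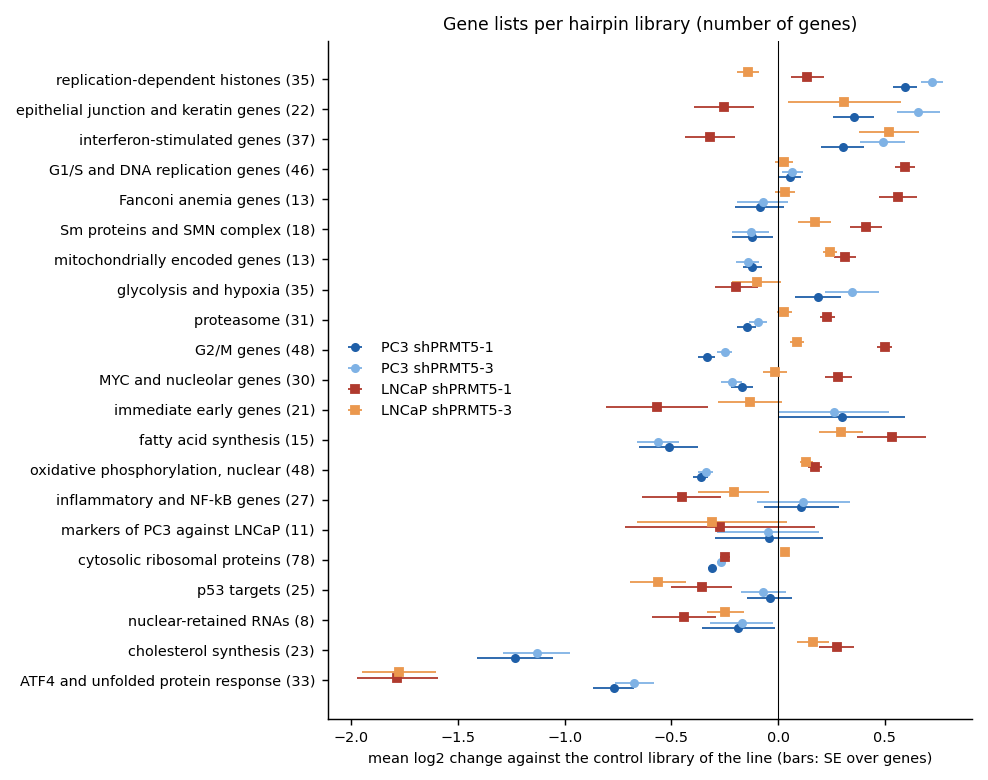
Mean log2 change of each gene list called over both lines, in PC3 or in LNCaP, for each hairpin library against the control of its line; points are means over the list's genes and bars are standard errors over genes, which are not replicates. The ATF4 and unfolded protein response genes lie at -0.77 and -0.67 in PC3 and at -1.78 and -1.78 in LNCaP.

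Within PC3 the naming rule took genes by the smaller of their changes in the 2 hairpin libraries, and those below 0 were expressed in the control library and nearly silent with both hairpins. The androgen receptor gene AR (ENSG00000169083, chromosome X, 67544032 to 67730619) had 708 normalized counts with shNC and 6.70 and 5.24 with the hairpins (log2 change -6.68 ± 0.33, adjusted p 0.0768), although the label gives PC3 as receptor negative. CHRDL1, a secreted BMP antagonist, had 699 against 2.51 and 2.10 (-7.73 ± 0.37, adjusted p 0.0768). MAP7D3 had 1286 against 12.6 and 19.9, NLGN4X had 448 against 5.86 and 3.15 and PLD5 had 410 against 2.51 and 3.15. In the other direction TENM2, a teneurin adhesion protein gene, stood at 14.2 with shNC and at 318 and 377 with the hairpins (4.52 ± 0.47). The immediate early gene EGR1 stood at 13.1 against 353 and 247 (4.39 ± 1.14). CACNA1S, ZSWIM5 and LONRF2 had log2 changes of 3.47, 3.13 and 3.29. None of these passed the limma threshold in PC3, while edgeR called 4 genes lower, CHRDL1, AR, MAP7D3 and CNTN1 (adjusted p 0.0284 to 0.0378).

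Of the lists, 6 fell and 4 rose in PC3. Cholesterol synthesis genes fell, 22 of 23 members being below 0, 15 passing over the list alone and 16 at least 1.5-fold lower in both hairpin libraries (mean -1.18, adjusted p 2.37e-14, adjusted p = 0.486 with an estimated correlation). The low-density lipoprotein receptor gene LDLR, at 8179 normalized counts in the control, had a log2 change of -1.57 ± 0.13, the squalene synthase gene FDFT1 had -1.39 ± 0.17, and SREBF2, which encodes the sterol-responsive transcription factor, had -1.05 ± 0.22. Fatty acid synthesis genes fell as well (14 of 15 below 0, 2 over the list alone, mean -0.54, adjusted p 0.000326, adjusted p = 0.486 with an estimated correlation). The desaturase gene SCD stood at -1.65 ± 0.15 and FASN at -0.82 ± 0.15. The unfolded protein response list fell (29 of 33 below 0, 21 over the list alone, mean -0.72, adjusted p 1.54e-12, adjusted p = 0.466 with an estimated correlation). Histone genes rose, 34 of 35 being above 0 and 17 passing over the list alone (mean 0.66, adjusted p 3.69e-14, adjusted p = 0.921 with an estimated correlation). HIST1H1E stood at 0.74 ± 0.14 and HIST1H1C at 0.49 ± 0.17. Most mRNAs of this list lack poly(A) tails, as ribosomal RNA does, and nuclear ribosomal RNA took 5.91e-05% of reads in the PC3 control against 0.00175 and 0.00143% with the hairpins. The ribosomal RNA gene RNA5-8S5 (ENSG00000277739.1), chosen after its values were seen, had 3.27 normalized counts against 295 and 210. Its reads are part of that ribosomal share and no separate evidence. The list of small structural RNAs was not called in PC3 (means 0.17 and 0.13 with the hairpins, camera adjusted p 0.764). Whether RNA without poly(A) tails accounts for the histone rise was not tested. Epithelial junction and keratin genes rose (18 of 22 above 0, 5 over the list alone, mean 0.51, adjusted p 3.83e-05, adjusted p = 0.921 with an estimated correlation). The E-cadherin gene CDH1 stood at 1674 in the control and 3019 and 3306 with the hairpins (0.92 ± 0.14). Oxidative phosphorylation (45 of 48 below 0, mean -0.35), cytosolic ribosomal protein (75 of 78, -0.29) and G2/M genes (41 of 48, -0.29) fell with 0 members passing over the list alone. Interferon-stimulated genes (27 of 37 above 0, mean 0.40, 1 over the list alone) and glycolysis and hypoxia genes (25 of 35, 0.27, 0 over the list alone) rose. The adjusted p of these 5 lists lay between 4.16e-10 and 0.0168, and between 0.466 and 0.921 with an estimated correlation. Without PC3 shPRMT5-3 the interferon-stimulated (0.30) and glycolysis calls (0.19) ended, and without either LNCaP hairpin library the glycolysis call ended at an unchanged mean of 0.27. All these PC3 values rest on the single control library, in which AR stood at 708, so they hold any other difference between control and hairpin cells besides the knockdown.

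limma called 0 genes in PC3, with 2707 at an unadjusted p under 0.05 against 875 by chance. Most of that excess was lost when PC3 shPRMT5-1 or PC3 shPRMT5-3 was left out, and it grew without either LNCaP hairpin library. In PC3 edgeR called 4 genes and DESeq2 called 373, 155 higher and 218 lower. By size, 1906 genes were at least 1.5-fold higher and 1339 at least 1.5-fold lower in both hairpin libraries. Simulated unchanged libraries sharing the control gave 472 and 369. They were drawn with the spread between the 2 PC3 hairpin libraries, which holds no difference between control and hairpin cultures. The excess therefore does not separate the knockdown from such a difference. The PC3 control also stood apart by chromosome position. On chromosome 12 between 38316578 and 47833132, 27 of 28 protein-coding genes with a mean of at least 50 were lower in both hairpin libraries, with medians of -1.18 and -1.33, while the next 20 genes had medians of 0.23 and 0.22. CNTN1 (1677 to 99.6 and 57.7 normalized counts) lies in that block, and the amino acid transporter gene SLC38A2, also in the block, had 43936 in the control against 12488 and 13140. Both were chosen after their values were seen, as were the edges of the block and the limit of 0.4 below. Of 582 windows of about 20 neighbouring genes, 8 shifted by at least 0.4 in the same direction in both PC3 hairpin libraries, while shuffled gene orders gave at most 2 and LNCaP gave 0.

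**Figure D3:**
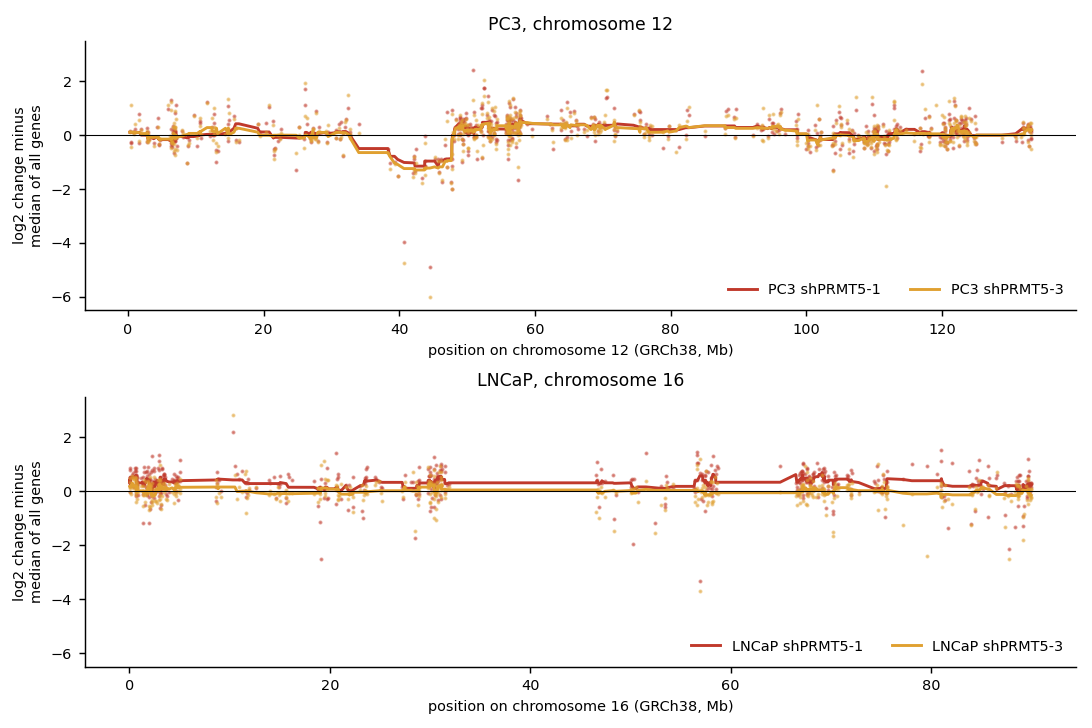
Log2 change against the control of the line minus the median of all genes, for protein-coding genes with a mean normalized count of at least 50, along chromosome 12 in PC3 and chromosome 16 in LNCaP (GRCh38); points are genes and lines are running medians over neighbouring genes. Both PC3 hairpin libraries drop between 38.3 and 47.8 Mb, and the chromosome 16 median is 0.33 in LNCaP shPRMT5-1 and 0.034 in LNCaP shPRMT5-3.

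Within LNCaP, by the same rule, TXNIP, whose product restrains glucose uptake (ENSG00000265972, chromosome 1, 145992435 to 145996600), stood at 253 normalized counts in the control and at 7878 and 6142 with the hairpins (log2 change 4.77 ± 0.22, adjusted p 0.0982). DDIT3, which encodes the stress transcription factor CHOP, had 3422 against 169 and 194 (-4.23 ± 0.28). CHAC1 had 968 against 37.4 and 67.4 (-4.24 ± 0.40), HERPUD1 had 15450 against 1520 and 1197 (-3.52 ± 0.19) and FAM129A had 1724 against 57.4 and 111 (-4.41 ± 0.41), each with an adjusted p of 0.0982. The heat shock gene HSPA6 had -3.01 ± 0.35. The other values above 0 were those of the glucuronosyltransferase genes UGT2B28 (3.49 ± 0.44) and UGT2B11 (3.58 ± 1.11, 2.27 without shPRMT5-3), near-identical paralogs among which the authors' counting could split reads, of CD163L1 (2.44 ± 0.65) and of the ketogenic enzyme gene HMGCS2, at 249 in the control and 1041 and 4830 with the hairpins. None passed the limma threshold.

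Of the lists, 10 rose and 7 fell in LNCaP. The unfolded protein response list fell, with 32 of 33 members below 0, 30 passing over the list alone and 29 at least 1.5-fold lower in both hairpin libraries (mean -1.78, adjusted p 1.62e-45, adjusted p = 0.253 with an estimated correlation). It was the only list in any comparison that fry called, at an adjusted p of 0.0275, which tests whether the genes move 1 way rather than against other genes. The p53 targets fell (19 of 25 below 0, 1 over the list alone, mean -0.46, adjusted p 0.000172, adjusted p = 0.640 with an estimated correlation). GDF15, a stress-induced cytokine gene, stood at 25302 in the control and 8706 and 14770 with the hairpins. Proliferation lists rose, G2/M genes with 44 of 48 above 0 (mean 0.29, adjusted p 1.30e-06) and G1/S and DNA replication genes with 43 of 46 (mean 0.31, adjusted p 6.77e-05), 0 members passing over the list alone in either (adjusted p = 0.979 with an estimated correlation, for both). With shPRMT5-1 the G1/S and G2/M list means were 0.59 and 0.50, against 0.025 and 0.088 with shPRMT5-3. Fatty acid synthesis (15 of 15 above 0, mean 0.41) and cholesterol synthesis genes (18 of 23, 0.22) rose with 0 members over the list alone, with adjusted p of 0.000714 and 0.00319 (adjusted p = 0.640 and 0.790 with an estimated correlation). DHCR24 stood at 0.81 ± 0.20 and LDLR at 0.79 ± 0.13. The other rising lists, with 0 members over the list alone, were mitochondrially encoded genes (mean 0.28), Sm proteins and the SMN complex (0.29), oxidative phosphorylation (0.15), Fanconi anemia genes (0.30), MYC and nucleolar genes (0.13) and the proteasome (0.13). The other falling ones were ribosomal proteins (-0.11), nuclear-retained RNAs (-0.34), inflammatory and NF-kB genes (-0.33), immediate early genes (-0.35) and markers of PC3 (-0.29, 1 higher and 4 lower over the list alone), many of whose members were near 0 in LNCaP. Their adjusted p ran from 0.000568 to 0.0412, and from 0.640 to 0.985 with an estimated correlation. The means with shPRMT5-1 and shPRMT5-3 were 0.56 and 0.033 for Fanconi anemia genes, 0.28 and -0.015 for MYC and nucleolar genes, 0.23 and 0.029 for the proteasome, and -0.25 and 0.032 for ribosomal proteins. They were 0.41 and 0.17 for Sm proteins and the SMN complex, -0.45 and -0.21 for inflammatory and NF-kB genes, and -0.57 and -0.13 for immediate early genes. Androgen receptor targets were not called in LNCaP (mean 0.14, adjusted p 0.724) or PC3 (mean 0.13, median -0.03, adjusted p 0.650), nor were DNA double-strand break repair genes (0.10 and -0.06, adjusted p 0.238 and 0.670). The LNCaP means with shPRMT5-1 and shPRMT5-3 were 0.47 and -0.18 for androgen receptor targets and 0.25 and -0.046 for break repair.

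limma and edgeR called 0 genes in LNCaP, with 1493 by limma at an unadjusted p under 0.05 against 875 by chance, and DESeq2 called 181, 31 higher and 150 lower. The limma count fell below the chance number without either PC3 hairpin library, and rose without either LNCaP hairpin library. Without LNCaP shPRMT5-1 the lists called dropped from 17 to 3, and of the 17 only the unfolded protein response and p53 targets were among the 3. Without PC3 shPRMT5-1 or PC3 shPRMT5-3, which enter only through the spread, 12 lists were called, Fanconi anemia, MYC, proteasome, immediate early and PC3 marker genes being lost. The PC3 marker call also ended without LNCaP shPRMT5-3 (-0.27). By size 766 genes were at least 1.5-fold higher and 932 lower in both hairpin libraries, fewer than the 1480 and 1247 of simulated unchanged libraries drawn with the spread between the LNCaP hairpins.

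The effect in PC3 was then set against that in LNCaP, since the lines differ in their labelled androgen receptor status. The PC3 side of this contrast rests on the control library that held AR and from which 8 windows of neighbouring genes were shifted alike. That side therefore holds any difference between control and hairpin cells besides the knockdown, and the parts could not be separated. The genes that the naming rule took were, below 0, AR (-6.72 ± 0.46, PC3 minus LNCaP), CHRDL1 (-7.27 ± 0.53), PLD5 (-9.44 ± 0.94), MAP7D3 (-5.89 ± 0.57) and the transcription factor gene LEF1 (-5.94 ± 0.68). PLD5 had only 0 reads in the LNCaP control and 10 and 3 with the hairpins. Its difference ran from -12.8 to -5.70 over the alternatives that kept all libraries. Above 0 they were TENM2 (5.36 ± 0.66), FAM129A (5.04 ± 0.58), SHH (4.80 ± 0.75), FER1L6 (4.54 ± 0.76) and BCL11B (4.43 ± 0.85). limma called 0 of 17509 genes (lowest adjusted p 0.199), with 2040 at an unadjusted p under 0.05 against 875 by chance. Leaving out either PC3 hairpin library took this count below the chance number, and leaving out either LNCaP hairpin library raised it. edgeR called 0 and DESeq2 called 152, 90 higher and 62 lower. Of the lists 16 differed between the lines with a preset correlation. Cholesterol synthesis differed most, at -1.40 with 23 of 23 members below 0 and 16 passing over the list alone (adjusted p 1.63e-15). The unfolded protein response fell less in PC3 by 1.06 with 28 of 33 members above 0 and 19 over the list alone (adjusted p 2.16e-14). These calls were lost with an estimated correlation (adjusted p = 0.422 and 0.397). Without LNCaP shPRMT5-1 8 lists were called.

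Across genes, which are not independent replicates, the mean knockdown effects of PC3 and LNCaP were nearly unrelated (Pearson r 0.052, Spearman rho 0.066 over 17509 genes). In all 4 hairpin libraries 156 genes were at least 1.5-fold higher and 147 lower, where independent lists of the sizes found in the 2 lines gave 83.4 and 71.3 and simulated unchanged libraries 62.5 and 42.5. By the same rule 114 genes were higher in PC3 and lower in LNCaP, and 69 the reverse. For these, independent lists gave 101 and 58.6 and simulated libraries 53.25 and 52.25. Exceeding the simulated counts therefore does not show a change common to the lines. Against independent lists the excess was larger for genes changed alike. The changes with the 2 hairpins correlated within PC3 (r 0.83, covariance 0.41, against 0.52 and 0.091 for unchanged libraries sharing the control) and less within LNCaP (r 0.35, covariance 0.16, against 0.50 and 0.28). The unchanged libraries were drawn with the spread between the hairpins of a line. The higher PC3 values can therefore hold any difference of the single control culture. The direct comparison of hairpin 1 with hairpin 3 over both lines gave 0 calls by limma and edgeR, with 569 genes by limma at an unadjusted p under 0.05, and 2 by DESeq2, COLCA1 and NFASC, both lower with hairpin 1. The count of 569 rose without either PC3 hairpin library and fell without either LNCaP hairpin library. Between the hairpins 14 lists were called with a preset correlation, 7 higher and 7 lower with hairpin 1, and 0 with an estimated correlation (adjusted p = 0.743 to 0.804). Interferon-stimulated genes were lower with hairpin 1 (33 of 37 members, mean -0.51, adjusted p 8.85e-08), the only one of these calls that held without each library in turn, at -0.20 without LNCaP shPRMT5-1 and -0.83 without PC3 shPRMT5-1. The interferon means with hairpins 1 and 3 were 0.30 and 0.49 in PC3 and -0.32 and 0.52 in LNCaP. G1/S and DNA replication genes were higher over the pooled lines (46 of 46, mean 0.28, adjusted p 3.27e-10), with 0 members over the list alone in either. Against the control, the G1/S means with hairpins 1 and 3 were 0.055 and 0.067 in PC3 but 0.59 and 0.025 in LNCaP, and without LNCaP shPRMT5-1 the difference was -0.0010. The other lists with a pooled mean above 0 were G2/M genes (0.16), MYC and nucleolar genes (0.17), double-strand break repair (0.15), androgen receptor targets (0.29), Fanconi anemia genes (0.26) and SR proteins and hnRNPs (0.11). Those below 0 were ribosomal proteins (-0.16), epithelial genes (-0.43), glycolysis and hypoxia (-0.13), small structural RNAs (-0.44), apoptosis regulators (-0.21) and fibroblast markers (-0.77). Whether the hairpin difference itself differed between the lines was not tested. In PC3 the means with hairpins 1 and 3 were -0.34 and -0.25 for G2/M genes, 0.095 and 0.17 for androgen receptor targets and -0.054 and -0.061 for break repair. For fibroblast markers, of which 5 were tested, they were 0.54 and 0.39 in PC3 and -0.79 and 0.90 in LNCaP, and for small structural RNAs 0.17 and 0.13 in PC3 and -0.78 and 0.13 in LNCaP.

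Without LNCaP shPRMT5-1 9 lists were called, 4 of them among the 14, and the G2/M mean was -0.17, break repair 0.0039, androgen receptor targets 0.011, MYC genes -9.1e-05 and Fanconi anemia genes -0.040. Fibroblast markers were then at 0.022, small structural RNAs at 0.044, apoptosis regulators at -0.010 and glycolysis and hypoxia genes at -0.048, not called, and epithelial genes at -0.22, still called. Without LNCaP shPRMT5-3 11 lists were called, 6 of them among the 14, and androgen receptor targets were at 0.016 and ribosomal proteins at -0.028. The calls of fibroblast markers (-0.18), small structural RNAs (-0.20), apoptosis regulators (-0.14), break repair (0.084) and Fanconi anemia genes (0.15) ended too, while glycolysis and hypoxia genes (-0.26) and G1/S genes (0.12) were still called. Without PC3 shPRMT5-3 the calls of glycolysis and hypoxia (-0.00024), epithelial genes (-0.41) and apoptosis regulators (-0.28) ended, and the means of fibroblast markers, small structural RNAs, ribosomal proteins, androgen receptor targets and G1/S genes were -1.36, -0.67, -0.30, 0.56 and 0.43. Without PC3 shPRMT5-1 the means were -1.56 for fibroblast markers, -0.91 for small structural RNAs, -0.65 for epithelial genes, -0.41 for apoptosis regulators and -0.21 for glycolysis and hypoxia. They were 0.56 for androgen receptor targets, 0.56 for G1/S, 0.50 for G2/M, 0.30 for break repair, 0.55 for Fanconi anemia and 0.35 for MYC genes. The call of SR proteins and hnRNPs ended without any of the 4 hairpin libraries (0.084 to 0.14). Without PC3 shPRMT5-1 limma called 198 genes between the hairpins, 54 higher and 144 lower, and without PC3 shPRMT5-3 it called 8.

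**Figure D4:**
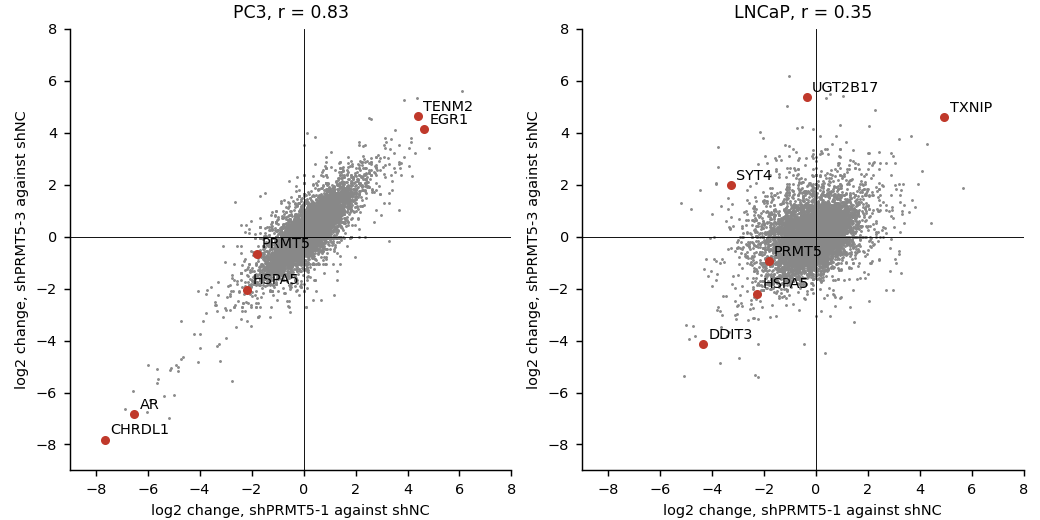
Log2 change with shPRMT5-3 against that with shPRMT5-1, each against the control of the line, for 17509 genes in PC3 and in LNCaP; each point is a gene, and named genes are in red. The points follow the diagonal in PC3 (r 0.83) and spread widely in LNCaP (r 0.35), where UGT2B17 and SYT4 lie far off it.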

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

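The tests of scaling and of glucose shortage were chosen after the result was seen; the graded effect of PRMT5 was set down before. The difference between the lines singled out 16 lists, each as the mean log2 change in PC3 minus that in LNCaP and each called by camera with a preset correlation. Cholesterol synthesis (-1.40), fatty acid synthesis (-0.95), G2/M genes (-0.59), oxidative phosphorylation (-0.50), Sm proteins and the SMN complex (-0.42), mitochondrially encoded genes (-0.41), MYC and nucleolar genes (-0.33), the proteasome (-0.25) and ribosomal proteins (-0.18) lay lower in PC3. The unfolded protein response (1.06), replication-dependent histones (0.66), immediate early genes (0.63), epithelial junction and keratin genes (0.48), inflammatory and NF-kB genes (0.45) and glycolysis and hypoxia genes (0.42) lay higher in PC3. The androgen receptor and its cofactors had a mean of -0.081 and a median of 0.38, and camera gave the direction of the median, but this call ended without any of the 4 hairpin libraries (mean -0.16 to -0.0052, adjusted p 0.0597 to 0.152). Only cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, G2/M, histone and unfolded protein response calls held without each hairpin library in turn. Without LNCaP shPRMT5-1 8 lists were called, and the epithelial difference was 0.19 and the MYC difference -0.18. Without LNCaP shPRMT5-3 the ribosomal protein difference was -0.042 and not called. Over the 4 fits without 1 hairpin library, that difference ran from -0.32 to -0.042. The G2/M difference ran from -0.79 to -0.38, that of the proteasome from -0.35 to -0.15 and that of immediate early genes from 0.41 to 0.85. None of the 16 was called with an estimated correlation (adjusted p 0.397 to 0.866). The PC3 control held AR at 708 normalized counts against 6.70 and 5.24 with the hairpins, and 8 windows were shifted alike, so any difference between the PC3 control and hairpin cells other than the knockdown is part of all 16 values.

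The unfolded protein response genes were lower in all 4 hairpin libraries, and by more in LNCaP. Scaling of the libraries was argued against, since 1 factor per library moves all genes alike and the list mean lay at -1.24 ± 0.11 (over genes) from the median of the other tested genes. Glucose shortage in the LNCaP control culture remained a candidate explanation: TXNIP and ARRDC4, genes that glucose induces, were both higher in the LNCaP hairpin libraries, the lowest of their changes being 1.11, while in PC3 the higher hairpin mean of these genes was 0.703, with TXNIP itself at -0.02 and 0.26, which left the matter open there. A graded effect of the remaining PRMT5 cannot be told apart from none, because hairpin 1 minus hairpin 3 was -0.053 ± 0.045 for the list: PC3 went with the explanation (-0.098 ± 0.039) and LNCaP was near 0 (-0.0071 ± 0.066), the errors being over genes, which are not replicates. An effect of PRMT5 itself may contribute as well, but with 1 control culture per line it was not separable from the state of that culture.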

How the results depend on the processing

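Of 1178 alternatives for 92 gene results, 1106 kept direction and side of the threshold, 65 passed it newly (52 with DESeq2), 7 no longer passed and 0 reversed. The 7 were those of HSPA5, which was called with every other setting but not with the mean of the line effects (adjusted p 0.0995) or without any single library (log2 change -2.24 to -2.11, adjusted p 0.104 to 0.507). Genes called over both lines numbered 3 with no filter (HSPA5, HSP90B1, MANF), 295 with DESeq2, 0 with the mean of the line effects and 0 to 0 leaving out libraries. DESeq2 called 373 in PC3, 181 in LNCaP, 152 for the difference and 2 between hairpins, and edgeR 4 in PC3, and the cause of these gaps was not tested. With the hairpin number as a replicate block, 28 genes were called for the difference (12 higher, 16 lower, lowest adjusted p 0.0047), AR, CHRDL1, PLD5, MAP7D3, LEF1, TENM2, FAM129A and BCL11B among them, against 0 without it, and 1 over both lines. The lines share the hairpin constructs, but hairpin differences correlated at only 0.075 between them, so the fit without the block was kept as planned. Leaving out libraries gave 0 to 198 genes between hairpins (198 without PC3 shPRMT5-1, 8 without PC3 shPRMT5-3). Lists called fell to 0 in every comparison with an estimated correlation, and with fry to 0 except 1 in LNCaP. The loss with an estimated correlation cannot be put down to correlation alone, since that test has only 2 or 3 residual degrees of freedom. Fatty acid synthesis in PC3, at an estimated correlation of -0.059, went from a camera p of 6.85e-05 to 0.0511. Other lists had high estimated correlations, such as 0.93 for G1/S genes in LNCaP. The list alternatives that follow were chosen after seeing the data. Leaving out libraries gave 7 to 17 lists over both lines (17 without PC3 shNC), 9 to 11 in PC3, 3 to 22 in LNCaP (3 without LNCaP shPRMT5-1), 8 to 20 for the difference and 9 to 20 between hairpins (8 and 9 without LNCaP shPRMT5-1). Besides estimated correlation and fry, 443 of 543 list alternatives were the same, 97 lost the call and 3 reversed: leaving out libraries gave -1.18 to 0.22 for cholesterol synthesis and -0.35 to 0.15 for oxidative phosphorylation over both lines (0.22 and 0.15 without PC3 shNC, which leaves the LNCaP effect), and -0.17 to 0.50 for G2/M genes between hairpins (-0.17 without LNCaP shPRMT5-1). Genes changed 1.5-fold alike numbered 1224 in PC3, 596 in LNCaP and 50 in all 4 libraries at 2-fold, 1863, 880 and 167 at a mean of at least 50, and 994 in LNCaP and 125 in all 4 with a pseudocount of 10. In all 4 libraries these were 18 higher and 32 lower at 2-fold, 69 and 98 at a mean of at least 50, and 41 and 84 with a pseudocount of 10. In PC3 they were 811 higher and 413 lower at 2-fold, but 938 and 925 at a mean of at least 50. The correlation between the lines was 0.079 at a mean of at least 50, 0.074 with a pseudocount of 10 and 0.013 for shPRMT5-3 in PC3 with shPRMT5-1 in LNCaP. The comparisons within PC3 and LNCaP and their difference could not be fitted without the control of a line they use. Depth limits genes near 2.51 to 3.27 normalized counts.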

Other observations

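In this part the tests of LNCaP RNA, of the X chromosome, of counting error as the whole cause, of chromosome segments and copies and of a common hairpin effect were chosen after the result was seen. The LNCaP hairpin libraries stood as far from each other as from their control. UGT2B17, a glucuronosyltransferase gene, had 72.7 normalized counts with shNC, 56.5 with shPRMT5-1 and 3045 with shPRMT5-3. SYT4 had 3512, 365 and 13944, ABCA12 had 950, 202 and 6626, and the androgen receptor target FKBP5 had 3440, 8259 and 2950 in the same order. Other androgen receptor targets went either way. TMPRSS2 (17265, 9468 and 14696) and KLK2 (2599.5, 3096.9 and 3722.5) were lower with shPRMT5-1 than with shPRMT5-3. KLK3 (22436, 29553 and 19695) and NKX3-1 (13830, 17482 and 15868) were higher. On the autosomes and the X chromosome, 170 genes differed 8-fold or more, 35 higher and 135 lower with shPRMT5-1.

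Counting error, which strikes genes independently, was argued against as the whole cause, since 45 of the 170 genes had a near neighbour of the same direction, against at most 26 in 1000 random sets. A hairpin effect common to both lines was argued against as the whole cause, since the covariance with the PC3 hairpin difference was 4.04% of the LNCaP variance (r 0.075). Shifts of whole chromosomes were argued against as the whole cause, since chromosome medians removed 2.18% of the squared difference. A chromosome median cannot show changed copies of an arm or segment, so those were not covered. Regional changes stayed open by the count of near neighbours, though gene families such as UGT2B sit together. Over 11799 genes with a mean of at least 50, the variance was 23.7 times that of Poisson counting (4.38 in PC3). This argues against depth or counting error as a large part of the difference in those genes. The ratio sets single cultures against counting noise, so it names no other cause, and genes with fewer reads were not covered. For chromosome 16, 100% of 25 windows lay above the genome median in LNCaP shPRMT5-1 (median 0.33, adjusted p 0.000511, from the smallest p that the permutations can give, 1e-04). Copy number and the share of cells were not measured, and extra copies may be a candidate explanation for that shift, the largest of 92. The p alone does not single it out: 41 of the 92 tests were called, 18 at that same adjusted p, among them chromosome 2 in LNCaP shPRMT5-3 (0.18, 36 of 39 windows), chromosome 14 in LNCaP shPRMT5-1 (0.18, 18 of 19) and chromosome 9 in 3 libraries (0.16 to 0.17), and the permutations treat neighbouring genes as independent.

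In PC3, 52 genes on the autosomes and the X chromosome changed 8-fold or more alike in both hairpin libraries, 30 lower and 22 higher, many near 0 on 1 side. LNCaP RNA in the PC3 control was argued against: 41 genes restricted to LNCaP stood at a median of 0.0582% of their LNCaP level and KLK3 had 0 reads, while AR stood at 9.38%. Of the 30 lower genes 11 were X-linked (36.7% against 3.24% of tested genes, Fisher's exact test, two-sided, adjusted p 2.69e-08), and 4 of the 52 had a near neighbour of the same direction, where random sets gave 2 at the 95th percentile and 8 at most. A PRMT5 effect common to both lines cannot be told apart from none on the 14 lower genes expressed in LNCaP (median -0.37 ± 0.25). PC3 control and knockdown cells may also have differed in chromosome segments, with 8 windows shifted alike (at most 2 in shuffled orders). The histone cluster was 1 of the 8. Of the 52 genes 5.77% lay inside these windows, which argues against the 8 windows as the cause of most of the 52. Smaller segments were not tested, since a median over a window of neighbouring genes cannot show the loss of a single gene. CNTN1, in the lowered block of chromosome 12, was counted outside the windows. The share expected by chance was not computed.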
